A study of Mus musculus with 257 samples.

How the data were processed

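RNA was sequenced from mouse cerebellum at embryonic day 16.5, postnatal days 5 and 13 and from day 30 on (E16.5, P5, P13 and P30+), and from medulloblastoma tumours of mouse models. The deposited table holds raw counts per gene made by the authors, with 32075 genes and 257 libraries. Per the submitters' processing notes, reads were aligned to GRCm38 with HISAT2 and counted with featureCounts. Versions, the annotation release and the strand setting of the counting are not given in the sources used here. Whole numbers and library totals were tested on the table, and the values fit raw counts with no normalization.

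Each library's group came from the submitters' labels of genotype, age and tissue, which make 53 groups of 3 to 10 libraries. In the names, B stands for Blbp-Cre, a recombinase active in hindbrain progenitors, which the WT labels do not name. D stands for the floxed Ddx3x allele, FLY for males with 1 floxed copy, FL/FL for females with 2 and FLPlus for females with 1 floxed and 1 intact copy. BCP stands for the Wnt-model alleles of Ctnnb1 and Pik3ca, BPtch for the Shh-model allele of Ptch1, and WT is the control of the normal background. No label states a sequencing batch or, for the control groups, a sex. E16.5 labels carry an animal number shared by several embryos with a pup number after it, read here as a litter. The labels call the Wnt-model tumours implants. Replicate numbers follow the sample type label. For BPtch P5 replicate 2, BPtchD-FLY P30+ replicate 3 and BDCP-FLPlus P13 replicate 4 of that label another field gives a different number, and 1 BDCP-FLY implant labelled P10 was read as replicate 10. Animal numbers in the labels link some cerebella and tumours of the same animal.

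Counts were modelled with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr at its minimum count of 10 and total of 15, and the quasi-likelihood F-test, two-sided. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested are said to be called. Null names the FLY and FL/FL labels and not a measured loss of Ddx3x. The Ddx3x null comparisons set the mean of the FLY and FL/FL groups against the control of the same age and background, in a fit of all 4 genotypes of that age and background. FLY, FL/FL and FLPlus were also read out one at a time. Heterozygous and tumour-allele comparisons took the 4 ages together with age as a term. The difference of an effect between backgrounds was tested as an interaction in a fit of all 12 cerebellar groups of an age. Standard errors were taken as the log2 fold change over the square root of F.

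Levels are CPM, counts per 1e+06 counts of the library total, without TMM factors. The sign ± marks the SD of levels and the standard error of log2 fold changes. The 23 gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, once with a preset correlation of 0.01 between genes and once with the correlation estimated from the data. List p-values were adjusted over the lists of a comparison. The count of members adjusted over the list alone is given beside the count over all genes. The lists hold Wnt targets, Shh targets, p53 targets, proliferation genes, granule progenitor, granule neuron, Purkinje, inhibitory interneuron, astroglia, radial glia, oligodendrocyte, microglia, choroid plexus, vascular, meningeal fibroblast and blood markers, Hox genes, hindbrain progenitor factors, inflammasome, interferon, stress response, immediate early and sex chromosome genes. Tables were handled with the R package data.table (1.17.8), and gene positions and overlaps came from GENCODE M21 on GRCm38.

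Comparisons, lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule names the genes of the model alleles (Ddx3x, Ddx3y, Ctnnb1, Pik3ca, Ptch1 and Fabp7), and per comparison up to 8 largest rises and 8 largest falls among called genes with a mean log2 CPM of at least 1. It leaves out predicted genes and, for null comparisons, genes whose FLY and FL/FL folds differ in sign. It also names up to 4 members of each list with the smallest adjusted p. The text gives some of the genes that the rule allows. Axin2 where it was not called, Gli1 in BPtch cerebella and Gli1 and Mki67 in tumours were added after their values were seen. The close reading of FL/FL alone, the FL/FL to FLPlus contrast, scores of 3 neighbouring brain regions and the listing run as a block were also chosen after seeing the data. A listing run is one of the passes through the alphabet that the library titles make in the order of the deposit.

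Alternatives were DESeq2 1.42.0, its size factors in edgeR, no low-count filter, the replicate number as a block, an animal number as a block, all 12 groups of an age in 1 fit, FLY alone, FL/FL alone and each library left out in turn. Other splits of the same libraries were drawn with a fixed seed, 60 per comparison and 30 where ages were pooled. In counts simulated without group effects and with 200 genes changed in a known direction, the false share of edgeR calls was 5.1% for the P13 null comparison of the normal background and 8.79% for the Wnt-model tumours. That of DESeq2 was 15% and 27%. The p53 list was raised 1.5-fold in these counts as well. Genes were drawn independently of each other, so these shares leave out differences of tissue or donor that real libraries share across genes. At P13 edgeR recovered 38.8% of genes changed 1.5-fold, 82.1% of those changed 2-fold and 100% of those changed 4-fold.

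Library totals ran from 614465 to 92341867 counts with a median of 19719551, and no library was left out. Counts of reads without molecular identifiers are not independent molecules, so low counts bound counting error only. The pseudocount and the filter act on weak genes, and folds of genes near 0 in one group are given as levels instead. Reads of overlapping genes and of genes on the opposite strand cannot be separated where the counting did not use strand.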

Results

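The data set measured gene expression in 227 cerebella and 30 tumours of mice with and without floxed alleles of Ddx3x, an X-linked RNA helicase gene, for deletion in hindbrain progenitors. Of the cerebella, 79 came from the normal background, 72 from the Wnt-model background (activated Ctnnb1 and Pik3ca alleles) and 76 from the Shh-model background (a Ptch1 allele). Each background had 4 genotypes at E16.5, P5, P13 and P30+. Most groups held 5 libraries. Those of 4 were BDCP-FLY and BDCP-FLPlus at P30+ and BD-FLPlus at P13, and those of 3 were BCP, BDCP-FLPlus and BPtchD-FLPlus at E16.5, BDCP-FLPlus at P13 and BPtchD-FLFL at P30+. The tumours were 5 BCP and 10 labelled BDCP-FLY implants from the Wnt model, and 5 each of BPtch, BPtchD-FLY and BPtchD-FLPlus from the Shh model. Totals ranged from 614465 to 92341867 counts per library. Mitochondrial genes held 0.43% to 5.46% of counts and the 10 most abundant genes 2.48% to 8.6%. P-values measure the spread between these libraries.

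Ddx3x (ENSMUSG00000000787, chromosome X, 13280970 to 13294052, GRCm38) was lower in male cerebella labelled FLY and close to the control level at P13 and P30+ in females labelled FL/FL. In the normal background, WT cerebella held 404 ± 53.1 CPM at E16.5, 466 ± 97.5 at P5, 341 ± 27.9 at P13 and 378 ± 35.8 at P30+ (SD, n = 5 each). BD-FLY cerebella held 345 ± 28.4, 247 ± 14.7, 144 ± 29.97 and 167 ± 12.1 CPM at these ages. Ddx3x fell in FLY by 0.86 ± 0.12 on the log2 scale at P5 (adjusted p = 0.0139, lower in 5 of 5 libraries), by 1.25 ± 0.13 at P13 (adjusted p = 0.000334) and by 1.15 ± 0.08 at P30+ (adjusted p = 6.38e-08). The E16.5 value was -0.22 ± 0.11 and was not called. Libraries labelled FL/FL held 331 ± 14.9 CPM at P13 and 373 ± 19.6 at P30+, with log2 fold changes of -0.03 and 0.02. Their difference from FLY was itself called, 1.23 at P13 and 1.18 at P30+ (adjusted p = 0.000225 and 4.38e-08). FL/FL groups are female and FLY groups male, so this difference in an X-linked gene also follows sex. No label gives the sex of the controls, and sex was not separated from the deletion in these values. The P5 value of FL/FL was -0.46 ± 0.12 (adjusted p = 0.0601).

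In the Shh background the difference of FL/FL from FLY in Ddx3x was called at P5 and P13, and in the Wnt background at P30+. These differences also follow sex, and the BCP controls of the Wnt background were mostly male. BPtchD-FLY cerebella at P13 held 134 ± 23.8 CPM against 395 ± 44.0 in BPtch, a log2 fold change of -1.58 ± 0.12 (adjusted p = 7.46e-07). FL/FL lay 1.52 above FLY there (adjusted p = 1.36e-06). Ddx3x changed by -0.84 ± 0.22 in BPtchD-FLY at P5 (adjusted p = 0.0162, 0.0516 without BPtchD-FLY P5 replicate 1). That group includes the library labelled replicate 2, at 435.8 CPM of Ddx3x against 174 to 238.3 in the other BPtchD-FLY libraries. At P30+ the Ddx3x change was -1.69 ± 0.25 and missed the threshold (adjusted p = 0.0701). Levels varied within both groups there. BPtch P30+ replicate 2 held 390.3 CPM and the other BPtch libraries 534.8 to 764. BPtchD-FLY P30+ replicate 1, the library with the fewest counts, held 345 CPM and the other BPtchD-FLY libraries 129.2 to 202.7. BDCP-FLY cerebella fell by 0.83 ± 0.10 at P30+ (adjusted p = 0.00228), and their values of -0.54 at P5 and -0.48 at P13 were not called. Ddx3y (ENSMUSG00000069045, chromosome Y, 1260771 to 1286629), the Y-linked copy of the helicase gene, held 51.7 to 94.95 CPM on average in BD-FLY groups and 0.0353 to 0.148 CPM in FL/FL groups of that background. The library labelled BPtchD-FLY P5 replicate 2 held 1758 CPM of Xist, 0.303 of Ddx3y and 436 of Ddx3x, the profile of a female library with an undeleted Ddx3x level. The near absence of Ddx3y in FL/FL females bounds the reads of Ddx3x counted as Ddx3y, and the reverse exchange was not measured.

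**Figure D1:**
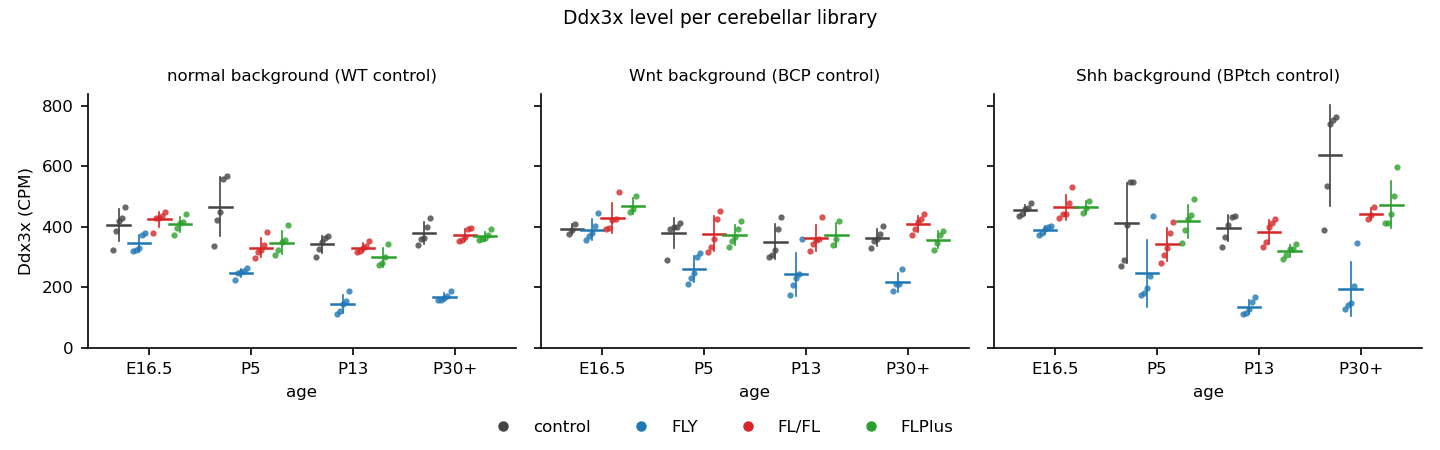
Ddx3x in CPM for each cerebellar library, by age, background and genotype, with bars for the group mean and SD. Male FLY libraries average below their controls from P5 on, at 144 CPM in BD-FLY against 341 in WT at P13, and libraries labelled FL/FL average 331 there.

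Normal development set the scale for the other comparisons. Between E16.5 and P30+ the WT cerebellum gained genes of mature neurons and glia and lost those of dividing progenitors. All 12 granule neuron markers rose with a median of 3.97, among them Cbln3 (9.50 ± 0.83) and Gabra6, a receptor subunit of granule neurons, which went from 0.512 ± 0.339 to 757 ± 106 CPM (SD, n = 5). All 11 Purkinje markers rose with a median of 4.58, including Gng13 (7.76) and Itpr1 (6.70), and 11 of 12 oligodendrocyte markers with a median of 6.00. Opalin, a myelin gene, was at 0 in every E16.5 library and at 16.3 ± 2.65 CPM at P30+. All 14 proliferation genes fell with a median of -4.68, Mki67 by 5.80 ± 0.42 and Top2a by 5.86 ± 0.39. Mki67 averaged 80.8 CPM at E16.5, 356 at P5, 52.6 at P13 and 1.25 at P30+. The progenitor genes Atoh1 (-8.83), Hes5 (-4.88) and Fabp7 (-2.87 ± 0.21) fell with 12 of 13 hindbrain progenitor factors (median -5.45) and 8 of 10 radial glia markers (median -1.46). All 13 Hox genes fell (median -8.03), as did the embryonic genes Fgf15 (-9.75) and Crabp1, whose level went from 32.9 to 0.0104 CPM. Astroglia markers rose in 9 of 10 cases (median 2.81, S100b 6.71, Gfap 5.43), immediate early genes in 8 of 10 (median 2.12, Fos 4.86) and interferon genes in 8 of 13 (median 1.41).

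In that comparison 12612 of 18988 genes were called, 6171 higher and 6441 lower at P30+. None of the list calls held with an estimated correlation. The adjusted p was then 0.0712 for radial glia markers and hindbrain factors, 0.0731 for astroglia, 0.299 for proliferation and oligodendrocyte genes, 0.31 for Purkinje markers, 0.328 for granule neuron and immediate early genes, 0.412 for Hox genes and 0.485 for interferon genes. List counts adjusted over the list alone equalled those over all genes.

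The tumour-predisposing alleles of the Wnt model, with Ddx3x intact, raised Wnt pathway targets in the cerebellum. Across ages, 14 of 15 targets rose in BCP against WT, with a median of 2.39, and the list call held with an estimated correlation (adjusted p = 0.0101). Notum (ENSMUSG00000042988, 5.12 ± 0.42) and Wif1 (4.94 ± 0.41), secreted Wnt inhibitors, and Rnf43 (2.62 ± 0.28), which removes Wnt receptors, were higher in 18 of 18 BCP libraries than the WT mean of their age. Tnfrsf19 rose by 2.56 and Axin2 (ENSMUSG00000000142, chromosome 11, 108920349 to 108950783), a feedback target of the pathway, by 1.41 ± 0.18. Axin2 averaged 84.4, 274, 188 and 55.5 CPM in BCP at the 4 ages, against 70.3, 58.0, 46.4 and 36.9 in WT. The largest rises also held Prss56 (7.79), Cyp2e1 (6.59), Esyt3 (5.55) and Rspo4 (5.39), a secreted Wnt agonist. The transcription factor gene Ptf1a (-2.38 ± 0.60), Prdm13 (-1.86), Lbx1 (-1.70) and Skor1 (-1.63) fell. Of 9 inhibitory interneuron markers 3 were called lower, including Pax2 (-0.89) and Kit (-0.93 ± 0.14), while the list was not called (median 0.04, adjusted p = 0.542). Microglia markers rose in 6 of 12 cases and 7 adjusted over the list alone, with Tmem119 at 2.58 ± 0.35 (median 0.37, adjusted p = 0.000398, and 0.903 with an estimated correlation). Single members of other lists were called too, such as Cxcr4 (1.71), Pmaip1 (1.35), Gjb6 (1.11), Casp1 (0.98) and Sox9 (-0.35).

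Of 20408 genes tested, 1779 were higher and 1509 lower in BCP than in WT. Fabp7 (ENSMUSG00000019874), whose promoter drives the Cre, fell by 0.89 ± 0.17 (adjusted p = 0.000363). Ctnnb1 (0.05 ± 0.05) and Pik3ca (0.17 ± 0.06) were not called, and the BCP controls were nearly all male, which the WT group was not.

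In BPtch cerebella of the Shh background some interferon response genes were higher than in WT, while the list call was lost with an estimated correlation (adjusted p = 0.407). Of 14 interferon response genes, 6 rose and 12 adjusted over the list alone, with a median of 0.68, among them the RNA sensors Ifih1 (0.76 ± 0.15) and Ddx58 (0.42 ± 0.10) and the effector Ifit1 (1.29 ± 0.34). Complement C4b (1.41), the antigen presentation gene Cd74 (1.24), Lcn2 (2.49) and the inflammasome protease gene Casp1 (0.83) rose, with 2 of 10 inflammasome genes called and 4 over the list alone (median 0.40). Of 10 immediate early genes, 2 were called lower and 3 over the list alone (median -0.52, Junb -0.54, Egr1 -0.65), and the list call was lost with an estimated correlation. Pax2, a gene of interneuron precursors, fell by 1.21 ± 0.30, and Axin2 (-0.28), Rbfox3 (-0.49) and Tnc (-0.65) were lower. Ptch1 (ENSMUSG00000021466, chromosome 13, 63508328 to 63573598) and its target Gli1 were not called, at 0.23 ± 0.13 and 0.36 ± 0.36. The BPtch libraries of P30+ were of different kinds: Gli1 ran from 21.32 to 364.6 CPM there, against 20.75 to 33.47 in WT of that age. BPtch P30+ replicates 3 to 5 held Mki67 in the range of the tumours, and they are part of this fit.

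In that comparison 615 genes were higher and 660 lower of 20024 tested. The count was 327 with the replicate number as a block and 4059 with scores of neighbouring regions in the model. It was 1953 without WT P13 replicate 3, 763 without WT P30+ replicate 1 and 845 without WT P30+ replicate 4. No list call held with an estimated correlation (adjusted p = 0.407 for inflammasome and 0.41 for immediate early genes). BPtch cerebella and WT cerebella lay in different listing runs, so batch and genotype cannot be told apart there. Catspere2 (-1.33) and Pcdhgb8 (-0.87) were also lower in BPtch, as they were at P13 in the mean of the normal-background cerebella labelled FLY and FL/FL.

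In the normal background the mean of the cerebella labelled FLY and FL/FL, called null by their labels, was compared with WT first. FL/FL showed no loss of Ddx3x at P13 and P30+, and held 424 ± 25.8 CPM at E16.5 against 404 ± 53.1 in WT, so this mean is not shown to measure the deletion. At E16.5, 40 of 18552 genes were called, all higher, among them Ptar1 (2.10 ± 0.41), Dgki (1.29 ± 0.24), Kalrn (0.89 ± 0.17), the DNA damage kinase gene Atm (0.87 ± 0.14) and the antisense RNA Kcnq1ot1 (0.80 ± 0.15), each higher in 10 of 10 libraries. Embryos of these groups share animal numbers, and the count was 123 with that number as a block and 3 with the replicate number as a block. Hox genes had a median of -0.80, an adjusted p of 0.00681 and one of 0.995 with an estimated correlation. The count ranged from 0 without WT E16.5 replicate 3 (edgeR, against 258 calls by DESeq2 with all libraries and 1491 genes at an unadjusted p under 0.05) to 281 without WT E16.5 replicate 1. It moved by more than 1.5 times without any library of the compared groups other than BD-FL-FL E16.5 replicates 2 and 5, BD-FLY E16.5 replicate 4 and WT E16.5 replicate 4.

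At P5 the clearest change lay in the libraries labelled FL/FL, in which p53 target genes rose. The 11 targets had a median log2 fold change of 0.93 against WT, and the list call held with an estimated correlation (adjusted p = 0.001). Over all genes 4 members were called and 7 adjusted over the list alone. Ccng1 (ENSMUSG00000020326, chromosome 11, 40748552 to 40755311), a cyclin gene induced by p53, rose by 1.49 ± 0.17 (adjusted p = 0.000227), from 54.7 ± 9.12 to 150 ± 41.6 CPM (SD, n = 5). Sesn2 rose by 1.12 ± 0.14, Phlda3 by 1.37 ± 0.32 and the cell cycle inhibitor gene Cdkn1a by 0.93 ± 0.19. In FLY the list had a median of 0.02, and FL/FL lay above FLY in the list test itself (median 0.68, adjusted p = 9.43e-05 with an estimated correlation). FL/FL also lay above the female FLPlus group (median 0.60, adjusted p = 0.000185 with an estimated correlation). Microglia markers rose in FL/FL in 5 of 12 cases and 8 over the list alone, among them C1qb by 0.77 (median 0.57, adjusted p = 0.192 with an estimated correlation). Etv4, an ETS transcription factor gene, rose by 1.42 ± 0.14 in FL/FL, from 32.9 to 85.4 CPM.

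**Figure D2:**
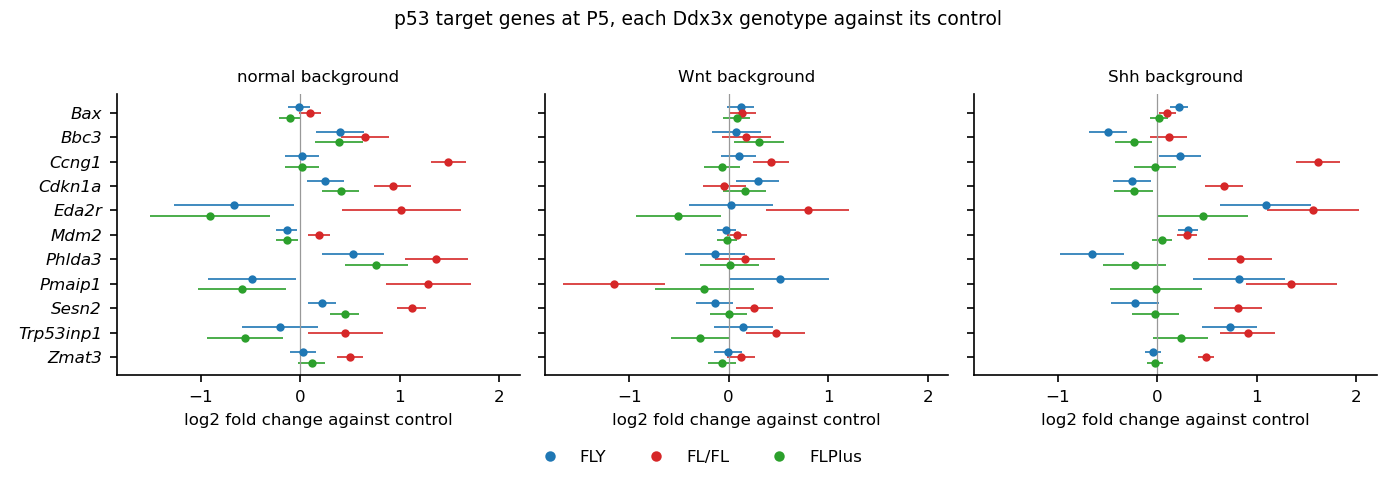
Log2 fold changes against the control at P5 for each of 11 p53 target genes in the libraries labelled FLY, FL/FL and FLPlus of each background, with error bars for the standard error. In the normal and Shh backgrounds the FL/FL points lie to the high side, with medians of 0.93 and 0.81.

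FL/FL called 291 genes at P5, 181 higher and 110 lower, and FLY called 2. The FL/FL count was 188 without BD-FL-FL P5 replicate 2, 149 without replicate 4, 183 without replicate 5, 161 without WT P5 replicate 1 and 152 without WT P5 replicate 3. The p53 list stayed called whichever library was left out. For the mean of both genotypes 2 of 18960 genes were called, Etv4 (0.84 ± 0.12) and Ddx3x (-0.66 ± 0.10), with the p53 list at a median of 0.40 (5 members over the list alone, adjusted p = 0.017 with an estimated correlation). Without 1 library that count ran from 0 (BD-FL-FL P5 replicate 2, and WT P5 replicates 1, 3 and 5, by edgeR; 1905 genes had an unadjusted p under 0.05 and DESeq2 called 121) to 19 (BD-FL-FL P5 replicate 1). Only BD-FL-FL P5 replicates 3 and 4 and BD-FLY P5 replicate 4 left it within 1.5 times. Proliferation genes (median -0.72), granule progenitor markers (-0.61), Shh targets (-0.36), astroglia (-0.54) and radial glia markers (-0.32) had preset adjusted p-values down to 7.05e-05 and lost their calls with an estimated correlation (adjusted p = 0.571 for proliferation genes, 0.588 for granule progenitor markers and Shh targets, 0.536 for radial glia and 0.53 for astroglia).

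At P13, 26 genes were higher and 19 lower of 18679 in the mean of the cerebella labelled FLY and FL/FL, the latter with Ddx3x at the WT level, a count of 45 that was 6 with the replicate number as a block and 230 with all 12 groups in 1 fit. The largest rises were Plac9a (3.29 ± 0.51), Plac9b (3.12 ± 0.50), Tmem254b (1.57 ± 0.24) and Dgkh (1.87 ± 0.32), all on chromosome 14. The largest falls were Pcdhgb8 (-1.80 ± 0.24) on chromosome 18, which overlaps other genes of its protocadherin cluster, and Catspere2 (-1.53 ± 0.23) on chromosome 1. Plac9a was as high in BD-FLPlus cerebella, at 7.06 CPM against 0.443 in WT. Plac9a and Plac9b are near-identical copies whose reads can be exchanged. Purkinje markers had a median of 0.60 with 1 of 11 called, Pcp4 (1.05 ± 0.21; adjusted p for the list 6.83e-08, and 0.712 with an estimated correlation). Interferon genes had a median of 0.45 (adjusted p = 0.712 with an estimated correlation) and rose in FL/FL alone with a median of 1.12, where 10 of 14 passed over the list alone (adjusted p = 0.143 with an estimated correlation). The count of 45 became 92 without BD-FL-FL P13 replicate 1, 27 without replicate 5, 22 without BD-FLY P13 replicate 1, 73 without replicate 2, 23 without replicate 4, 14 without WT P13 replicate 1 and 27 without WT P13 replicate 5.

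At P30+, 23 genes were higher and 70 lower of 17827. The midbrain score averaged -2.57 ± 0.15 in WT, -0.04 ± 2.52 in BD-FLY and -0.21 ± 3.2 in FL/FL, and the count of 93 was 2 with scores of neighbouring regions in the model and 12 with all 12 groups in 1 fit. Psmc3ip, a gene of homologous recombination, rose by 1.58 ± 0.24 (adjusted p = 0.00389), from 1.68 ± 0.520 CPM in WT to 5.44 ± 0.670 in BD-FLY and 4.48 ± 1.55 in FL/FL, with 1.63 in FLPlus. Sdk1 (1.23 ± 0.21) and Robo1 (0.77 ± 0.15), both genes of neuronal wiring, rose as well, and Mndal (2.29 ± 0.50) and its overlapping neighbour Ifi203 (1.83 ± 0.39) on chromosome 1. Gadd45b (-0.98 ± 0.15), a stress-inducible gene, Sertad1 (-0.93 ± 0.14), Msh5 (-1.41 ± 0.21), Insrr (-1.49 ± 0.27) and Col2a1 (-0.94 ± 0.21) fell in 10 of 10 libraries. Msh5 lies on chromosome 17 close to other called genes, such as Vars and H2-D1. Microglia markers had a median of 0.59 (adjusted p = 0.000953, and 0.894 with an estimated correlation). In FL/FL alone their median was 0.78, with 11 of 12 passing over the list alone and an adjusted p of 0.69 with an estimated correlation. The p53 list had a median of 0.25 and immediate early genes one of -0.42, with 2 and 4 members over the list alone (adjusted p = 0.894 for both with an estimated correlation). The count of 93 ran from 20 without WT P30+ replicate 4 to 646 without BD-FLY P30+ replicate 2, and moved by over 1.5 times without any library other than BD-FL-FL P30+ replicates 1, 3, 4 and 5 and WT P30+ replicate 5.

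In the Wnt background, several Wnt targets fell in cerebella labelled FL/FL at P30+. At that age Notum fell by 3.84 ± 0.56, Wif1 by 4.92 ± 0.73 and Apcdd1 by 2.93 ± 0.47 in FL/FL, and Notum averaged 4.23 ± 1.44 CPM against 59.5 ± 30.6 in BCP (SD, n = 5). Of 13 targets 6 were called and 10 passed over the list alone, with a median of -1.45 (adjusted p = 0.0668 with an estimated correlation). In FLY the list median was 0.78, Notum averaged 148 ± 68.5 CPM (n = 4), and the difference between FL/FL and FLY was called for Notum (-5.08), Wif1 (-6.18), Apcdd1 (-3.97) and Axin2 (-1.69, adjusted p = 0.0051). The change in FL/FL differed from that in the normal background for Notum (-3.53, adjusted p = 0.0166), Wif1 (-4.86) and Apcdd1 (-3.14). The midbrain score averaged 0.17 ± 2.87 in BCP and -2.21 ± 0.28 in FL/FL at P30+. With the region scores in the model FL/FL called 30 genes, and the targets had a median of -1.38 (adjusted p = 0.1 with an estimated correlation). At P5 the targets had a median of -1.19 in FL/FL, with 12 of 15 passing over the list alone and an adjusted p of 0.183 with an estimated correlation. Wif1 was at -2.57, Tnfrsf19 at -1.24 and Axin2 at -0.995, none called over all genes. At P13 the median was -1.60 with 5 over the list alone (adjusted p = 0.799 with an estimated correlation), and Axin2 averaged 74.0 CPM against 188 in BCP. The p53 list was not called in FL/FL (medians of 0.16, -0.07 and -0.09 at P5, P13 and P30+), and for Ccng1 at P5 the change lay 1.09 below that in the normal background (difference -1.09, adjusted p = 0.0327). Otog fell by 6.42 ± 0.90 in FL/FL at P30+.

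**Figure D3:**
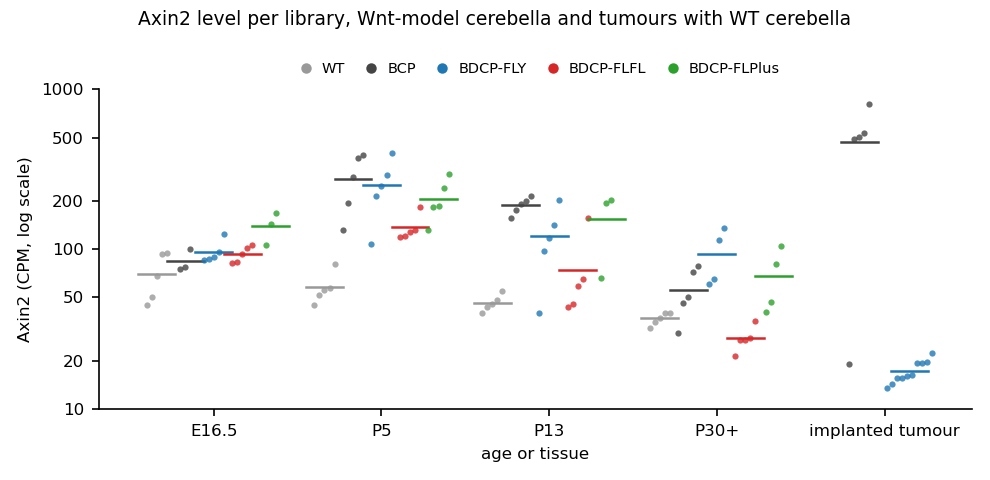
Axin2 in CPM for each WT and Wnt-background cerebellum by age and for each Wnt-model implant, on a log scale with bars for the group mean. Libraries labelled FL/FL average 138 CPM at P5 and 27.8 at P30+, against 274 and 55.5 in BCP.

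FL/FL called 63 genes at P5 and 64 at P30+ in the Wnt background. The P5 count ran from 14 to 221 and kept within 1.5 times without BDCP-FLFL P5 replicate 3 alone, and the P30+ count ran from 27 to 130 and kept within 1.5 times without BCP P30+ replicate 4 alone. For the mean of both genotypes the calls were few: 6 of 19055 at E16.5, 8 of 18913 at P5, 3 of 19167 at P13 and 9 of 18209 at P30+. At E16.5 the BCP embryos share no animal number with the null embryos. The calls were largely genes of the sex chromosomes, because the BCP controls were mostly male (list median -2.15 at E16.5, adjusted p = 0.092 with an estimated correlation, -2.25 and 0.0579 at P5, and -2.05 and 0.00935 at P30+). The P5 count was 37 without BCP P5 replicate 1 and 20 without BDCP-FLY P5 replicate 2. Counts at E16.5, P5 and P13 were higher by over 1.5 times with all 12 groups in 1 fit and by DESeq2. The P13 count ran from 0 in 12 of the left-out fits (edgeR; 2212 genes had an unadjusted p under 0.05 and DESeq2 called 158) to 29 without BDCP-FLFL P13 replicate 3, and held only without BCP P13 replicate 1. Gcnt4 rose by 1.40 ± 0.24 at P5. Axin2 in the mean of both genotypes was at 0.11, -0.56, -0.97 and -0.17 at the 4 ages and was not called. At P5 blood markers (median 1.62, 6 of 6 over the list alone, adjusted p = 0.133 with an estimated correlation) and at E16.5 choroid plexus markers (median 2.22, 7 of 11 over the list alone, 0.429) moved with the null groups. Meningeal (0.59, 0.574) and vascular markers (0.44, 0.574) moved with them at E16.5. Stress response genes had a median of -0.15 at P5 (adjusted p = 0.133 with an estimated correlation).

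In the Shh background at P5, p53 targets rose in the libraries labelled FL/FL as in the normal background. The list had a median of 0.81 (2 of 11 called, 9 over the list alone, adjusted p = 0.00352 with an estimated correlation), and it stayed called whichever library was left out. FL/FL lay above FLY in this list by a median of 0.53, which was not called with an estimated correlation (adjusted p = 0.785). The FLY group of that contrast includes the library labelled BPtchD-FLY P5 replicate 2, which has a female profile and an undeleted Ddx3x level. Ccng1 rose by 1.61 ± 0.22, from 57.9 ± 5.57 to 177 ± 15.9 CPM (SD, n = 5), and Zmat3 by 0.49 ± 0.08. The death receptor gene Tnfrsf10b rose by 1.67 ± 0.28 in the mean of both null genotypes, Traf4 by 1.13 ± 0.10 (adjusted p = 1.57e-05, higher in 10 of 10 libraries), Zbtb42 by 1.54 ± 0.21 and Cd109 by 1.27 ± 0.28. The fatty acid desaturase gene Scd1 fell by 1.14 ± 0.17, Scd2 fell by 0.59 ± 0.11, the sterol enzyme gene Tm7sf2 fell by 0.56 ± 0.11 and Myoc fell by 2.18 ± 0.37. In all, 132 genes were higher and 20 lower of 19570. The count became 260 without BPtch P5 replicate 1, 71 without replicate 2, 72 without replicate 3, 83 without replicate 4, 99 without BPtchD-FLFL P5 replicate 2 and 238 without BPtchD-FLY P5 replicate 4. It also fell by over 1.5 times with the region scores in the model and with the replicate number as a block.

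FLY alone called 4727 genes at this age and FL/FL 351, the latter 223 without BPtch P5 replicate 5. The FLY count was 3833 without the library labelled BPtchD-FLY P5 replicate 2, 960 without BPtch P5 replicate 2, 1599 without BPtch P5 replicate 3, 1827 without BPtchD-FLY P5 replicate 1, 2178 without BPtchD-FLY P5 replicate 3 and 7165 without BPtch P5 replicate 1. A score of midbrain genes moved with the FLY group: it was -0.51 ± 1.17 log2 CPM in BPtchD-FLY, with a range of -1.33 to 1.46, and 3.62 ± 1.43 in BPtch, with a range of 1.63 to 5.26. With scores of 3 neighbouring regions in the model, edgeR called 0 genes for FLY. Of the 4727 genes 1563 were higher and 3164 lower. Their median log2 fold change, each taken in its direction without the scores, went from 0.60 to 0.15. Proliferation genes had a median of 0.89 in FLY (adjusted p = 0.896 with an estimated correlation) and of -0.53 in FL/FL.

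**Figure D4:**
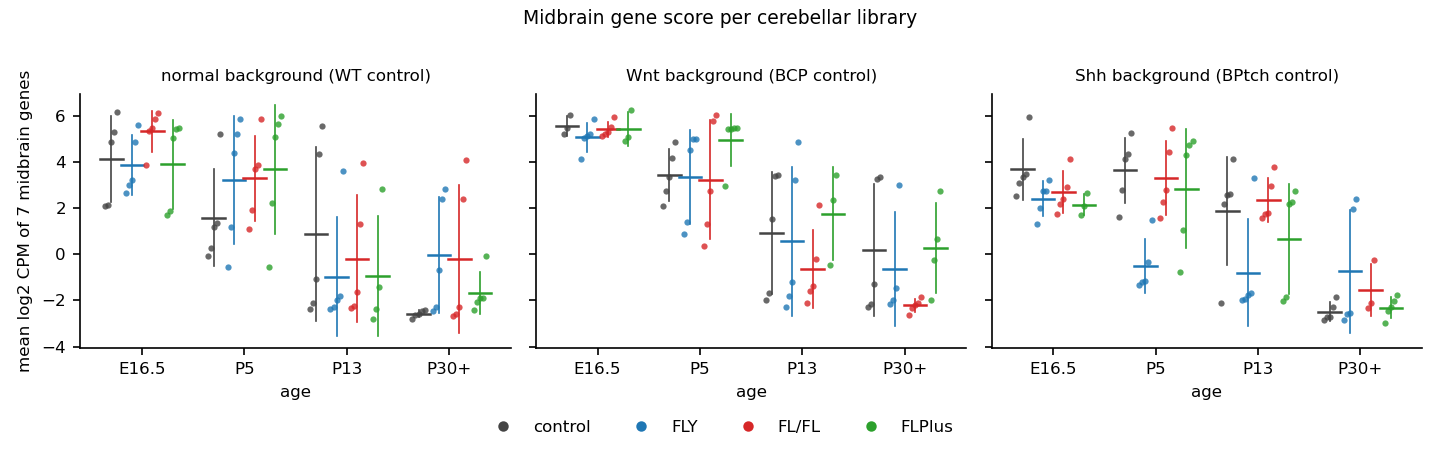
Mean log2 CPM of 7 midbrain genes in each cerebellar library, by age, background and genotype, with bars for the group mean and SD. At P5 the BPtchD-FLY libraries average -0.51 and the BPtch libraries 3.62.

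At P13 the Shh-background cerebella labelled FL/FL had higher microglia and interferon genes. Of 12 microglia markers 10 rose, with a median of 1.38 (10 over the list alone), among them Ctss (2.08 ± 0.31), Trem2 (1.82 ± 0.20, from 3.26 to 11.5 CPM) and Cd68 (1.24 ± 0.16). With an estimated correlation the adjusted p was 0.0491, and it lay under 0.05 without BPtchD-FLFL P13 replicate 1, 3 or 4 and above it without any other library. Interferon genes rose in 11 of 14 cases and all 14 over the list alone, with a median of 2.08 and Ifit1 at 3.22 ± 0.70 (adjusted p = 0.41 with an estimated correlation). The p53 list had a median of 0.37 with 5 of 11 called, 6 over the list alone, and an adjusted p of 0.0302 with an estimated correlation, or 0.0576 without BPtchD-FLFL P13 replicate 5. Cd109 (5.06 ± 0.57), the receptor gene Met (3.00 ± 0.35), Ddit4l (2.14 ± 0.24) and the integrin gene Itgam (1.78 ± 0.21) rose in FL/FL. Kit (-1.43 ± 0.13), a gene of cerebellar interneurons, Tfap2b (-1.37), Grm2 (-1.23 ± 0.16) and Myoc (-4.24 ± 0.47) fell. Kit was at 0.09 in FLY, and the difference of FL/FL from FLY was called (-1.53, adjusted p = 1.36e-06).

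BPtch P13 replicates 3 and 4 carry P14 in their titles, so the age of these controls is not certain. FL/FL called 1209 genes at P13, 802 higher and 407 lower, and FLY called 2. The FL/FL count was 719 without BPtchD-FLFL P13 replicate 1, 643 without replicate 3, 2313 without replicate 4, 2467 without BPtch P13 replicate 2, 675 without replicate 3, 780 without replicate 4 and 702 without replicate 5. For the mean of both genotypes 39 genes were higher and 13 lower of 19386, from 11 without BPtch P13 replicate 5 to 223 without BPtch P13 replicate 2, and the count moved by over 1.5 times without any library other than BPtchD-FLFL P13 replicates 2, 3 and 5 and BPtchD-FLY P13 replicate 5. It was lower by over 1.5 times with all 12 groups in 1 fit and higher by as much with the region scores in the model.

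At E16.5 in the Shh background, 12 genes were higher and 7 lower of 19832 in the cerebella labelled FLY and FL/FL. The count of 19 was 1 with the region scores, 4 with all 12 groups in 1 fit and 5 with the replicate number as a block. All 5 BPtch embryos share 1 animal number that no null embryo carries, so genotype and litter cannot be told apart. Samd11 fell by 1.55 ± 0.20 (adjusted p = 0.00235), from 8.72 ± 3.81 CPM in BPtch to 2.98 ± 0.545 in BPtchD-FLY and 2.96 ± 0.315 in FL/FL. Tshz3 (0.81 ± 0.15) and the chromatin gene Kmt2c (0.42 ± 0.08) rose, and Nudt16 fell by 0.38 ± 0.07. Hox genes had a median of 1.63 with 2 of 16 over the list alone (adjusted p = 0.519 with an estimated correlation). The count ran from 3 without BPtch E16.5 replicate 4 to 36 without BPtch E16.5 replicate 2, and moved by over 1.5 times without any library other than BPtch E16.5 replicates 1 and 3, BPtchD-FLFL E16.5 replicate 4 and BPtchD-FLY E16.5 replicate 1. At P30+ edgeR called 0 of 19953 genes, with 2383 at an unadjusted p under 0.05 and 21 called by DESeq2, while the fit of all 12 groups called 3187. Purkinje (median 0.72), interneuron (0.71), astroglia (0.62) and oligodendrocyte markers (0.81) lay higher and Shh targets (-1.74) lower in the null groups, with adjusted p = 0.532 for the first 4 and 0.642 for Shh targets with an estimated correlation. Of the 5 BPtch libraries at that age, replicates 3 to 5 held 979 to 1334 CPM of Mki67, in the range of the tumours. The animals of these replicates also gave BPtch tumour libraries.

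In libraries labelled FLPlus, with 1 floxed copy, Ddx3x lay near the control level and few other genes were called. Ddx3x was at -0.13 ± 0.07 in BD-FLPlus, 0.02 ± 0.06 in BDCP-FLPlus and -0.21 ± 0.08 in BPtchD-FLPlus against their controls, none called. The FLPlus groups are female, while the BCP controls were mostly male and the BPtch controls include males. For this X-linked gene, sex and loss of 1 copy cannot be told apart in the Wnt and Shh values. In the normal background 14 genes were higher and 10 lower of 19949, including Dgkh (1.26 ± 0.24), Arfgef3 (0.97), Slc16a7 (0.69) and St6galnac3 (0.46 ± 0.07). Oligodendrocyte markers had a median of 0.38 and proliferation genes one of -0.29 there (adjusted p = 0.588 for both with an estimated correlation). In the Wnt background 8 genes were higher and 13 lower of 20172, largely of the sex chromosomes, with the X genes Kdm6a (0.39 ± 0.05), Eif2s3x (0.47) and Kdm5c (0.33) higher in the female FLPlus group, and Kcnq1ot1 (-0.54) and Plag1 (-0.49) lower. In the Shh background 5 of 21283 genes were called, all lower, and 4 of them were the Y genes Ddx3y, Eif2s3y, Uty and Kdm5d, since FLPlus is female and the BPtch controls include males. Hox genes had a median of 1.13 with 6 of 16 over the list alone (adjusted p = 0.353 with an estimated correlation). Granule progenitor markers had one of 0.18 (0.442). The normal-background count of 24 became 58 without BD-FLPlus E16.5 replicate 3, 13 without BD-FLPlus P13 replicate 2, 14 without BD-FLPlus P30+ replicate 1, 60 without BD-FLPlus P30+ replicate 4, 47 without BD-FLPlus P5 replicate 1, 49 without WT E16.5 replicate 1 and 15 without WT P30+ replicate 4. It was lower with the replicate number as a block. With the region scores, with the listing run as a block and by DESeq2 it was higher.

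In Shh-model tumours the deletion was plain in Ddx3x and few other genes were called. BPtchD-FLY tumours held 110 ± 26.6 CPM of Ddx3x against 657 ± 78.1 in BPtch tumours (SD, n = 5), a fall of 2.57 ± 0.24 on the log2 scale (adjusted p = 0.000294). Heterozygous BPtchD-FLPlus tumours held 578 ± 186 CPM. For FLY 2 of 18373 genes were called, both lower, against 352 by DESeq2 and 2493 at an unadjusted p under 0.05. In counts simulated for this comparison edgeR recovered 19.4% of genes changed 1.5-fold, so small changes can be missed. The edgeR count was 5 without BPtchD-FLY tumour replicate 1 and 17 without replicate 5. Choroid plexus markers (median 3.99, 8 of 10 over the list alone) and meningeal markers (median 1.22, 3 of 10) lay higher in BPtchD-FLY tumours, with an adjusted p of 0.852 for both with an estimated correlation. For FLPlus 4 genes were called, all lower and among them Ddx3y (-8.16), since the FLPlus tumours are labelled female. That count fell to 0 without BPtchD-FLPlus tumour replicate 3 (edgeR; DESeq2 called 12 with all libraries, and 816 genes had an unadjusted p under 0.05). It moved by over 1.5 times without any library other than BPtch tumour replicates 1, 3 and 5, the highest value being 6. Between BPtch tumours and BPtch cerebella of P30+ edgeR called 0 of 18244 genes, with 1834 at an unadjusted p under 0.05 and 16 by DESeq2. Those cerebella were of different kinds, which widens the spread behind that count: replicates 1 and 2 held 0.951 and 1.78 CPM of Mki67 and replicates 3 to 5 held 979 to 1334, and the chi-square per degree of freedom was 503 to 572 between these sets, 15.4 between replicates 1 and 2 and 19.1 to 56.8 among the others. Tumour replicates 1, 2 and 3 share their animals with cerebella replicates 3, 5 and 4, which are the cerebella with high Mki67. With the animal as a block edgeR also called 0. Gli1 averaged 274 ± 106 CPM in the tumours and 190 ± 159 in those cerebella, and Mki67 906 ± 251 and 687 ± 639.

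The libraries labelled BDCP-FLY tumour differed from BCP tumours in most genes, and their Ddx3x level did not show the deletion. Ddx3x was at 518 ± 67.1 CPM (SD, n = 10) against 493 ± 94.2 in BCP tumours (n = 5), a log2 fold change of -0.09 ± 0.14. Wnt targets were lower, with 12 of 13 called and a median of -5.71: Axin2 fell by 4.95 ± 0.48, from 471 ± 285 to 17.3 ± 2.83 CPM, and Notum by 8.62 ± 0.80, from 413 to 1.18 CPM. Apcdd1 (-6.16), Tnfrsf19 (-6.15) and Wif1 (-9.32) were lower as well. All 14 interferon genes rose with a median of 3.25, Oasl2 from 54.1 to 581 CPM, Bst2 by 2.97 and Irf7 by 3.21. All 14 proliferation genes rose with a median of 1.92, Mcm5 from 31.9 to 239 CPM and Pcna by 1.75. The libraries labelled BDCP-FLY tumour also expressed Hoxd11, a gene of posterior body regions, at 34.3 ± 9.71 CPM, against 0.0126 CPM in BCP tumours. They held both Xist (423 ± 250 CPM) and Ddx3y (83.5 ± 28.7). Lhx9 (-8.29), the connective tissue gene Dcn (-5.82), Egr1 (3.45) and Trib3 (3.17) were called too. BCP tumour replicate 5 held 19.0 CPM of Axin2 and 575 of Gabra6, and Prl averaged 4890 ± 10930 CPM in BCP tumours, with a highest value of 24440.

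All 5 BCP implants share 1 number in their labels and the BDCP-FLY implants carry 3 others, so these p-values measure spread between implants and not between donor tumours. Among these tumours 5734 genes were higher and 4292 lower of 19471. No list call held with an estimated correlation (adjusted p = 0.734 for Wnt targets and interferon genes, 0.74 for proliferation genes). Vascular markers were lower in 9 of 10 cases (median -1.26) and microglia markers in 6 of 12 (median -1.06), with adjusted p = 0.734 and 0.74 with an estimated correlation.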

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

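The tests of sex, of neighbouring tissue, of reads of the deleted allele, of a wrong label, of neighbouring genes and of lost cells were chosen after the results they concern were seen. The close reading of FL/FL alone was too. What the Shh P5 FLY test had to show was set in 3 versions, 2 of them after its result was known. One version that also asked for the ratio of fold to error left the question undecided, and the version used here gives the outcome of the first.

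The first pattern is that libraries labelled FL/FL had p53 targets above WT at P5 in the normal background while Ddx3x lay at -0.46 ± 0.12 (adjusted p = 0.0601), and near the control level at P13 and P30+. Sex alone is argued against by the contrast with female FLPlus cerebella (adjusted p = 0.000185 with an estimated correlation), and neighbouring tissue by the contrast with WT under 3 region scores (adjusted p = 0.00152, median 0.84 against 0.93 without them). Reads of the deleted allele that are still counted are argued against by Ddx3x in FLY, at -1.25 at P13, while loss of cells without DDX3X in females, which have no Ddx3y, stays open: that FL/FL lay above FLY (adjusted p = 9.43e-05) restates the pattern, since the median of FLY was 0.02. In the Shh background that contrast depended on the test (median 0.53, adjusted p = 0.00976 with the preset correlation and 0.785 with an estimated one), and in the Wnt background the p53 median of FL/FL was 0.16 at P5. The Shh FLY group includes the library labelled BPtchD-FLY P5 replicate 2, which has a female profile. The contrast of FL/FL with FLY also follows sex and the number of floxed copies, no cell counts were measured, and a missing deletion in FL/FL would not by itself raise p53 targets.

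The second pattern is the 4727 genes called for BPtchD-FLY against BPtch at P5. A wrong label on replicate 2 as the whole cause is argued against, since 3833 genes were called without the library labelled BPtchD-FLY P5 replicate 2. Different amounts of neighbouring tissue may explain part of it, since with the region scores edgeR called 0 genes for FLY. The median log2 fold change of the 4727, each taken in its direction without the scores, went from 0.60 to 0.15. Their median standard error went from 0.17 to 0.18. These genes were chosen by the fit without scores, which favours larger folds there. The deleted gene lost its call too, with a larger fold (Ddx3x -0.84 ± 0.22, adjusted p = 0.0162, and -1.22 ± 0.30, adjusted p = 0.864 with the scores). A count of 0 therefore does not show that no gene changed. For the 4727 genes the folds shrank while the median error changed little, so lost power is not shown as the main reason. A change of the same genes by the deletion stays open.

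The third pattern is that genes called in the normal background lay next to each other, within 1 Mb. At P13 10 of 40 autosomal genes had a called neighbour, against a median of 2 and a highest value of 14 in 10000 lists matched for expression (permutation p = 0.0019), and at P30+ 38 of 90, against 12 and 29 (permutation p = 1e-04, the smallest they can give). A stretch of another strain's chromosome may explain some of these groups of genes. At P30+ they lay on chromosomes 1, 5, 7, 9, 11, 17 and 19, with Msh5 among those on chromosome 17. Most calls of that age were lost with the region scores. The random lists were not matched for gene density. Neither gene density nor neighbouring tissue was tested as a cause of the grouping. For the heterozygous comparison the test decides nothing, since 0 of 19 had a neighbour and the random lists also had a median of 0. At P13, reads shared between copies such as Plac9a and Plac9b cannot be told apart from it, because with each symbol stem counted once 4 genes had a neighbour (permutation p = 0.28).

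Other splits of the same libraries were drawn, 60 per comparison and 30 where ages were pooled, the real split counted among them. Chance is said to be excluded where a share under 0.05 of the splits called as many genes, uncorrected over the 22 comparisons. With so few splits this is a coarse bound. By it chance was excluded in the normal background at E16.5 (40 genes, highest other 1, 1 split with as many), P5 (2, 0, 1) and P13 (45, 0, 1), and at P30+ (93, highest other 556, 2 splits with as many). At normal P5 1 of the 2 genes was Ddx3x itself, and the count fell to 0 without certain single libraries. Chance was excluded in the Wnt background at P5 (8, 1, 1) and P30+ (9, 421, 2) and not at E16.5 (6, 26, 4) or P13 (3, 1292, 3). It was excluded in the Shh background at E16.5 (19, 2, 1), P5 (152, 3921, 2) and P13 (52, 5, 1). It was excluded for FLPlus in the normal (24, 5, 1), Wnt (21, 1, 1) and Shh background (5, 1, 1), for BCP (3288, 1, 1) and BPtch against WT (1275, 0, 1), for the Wnt-model implants (10026, 5783, 1) and for development (12612, 1258, 1). It was not excluded for the tumours BPtchD-FLY (2, 3545, 4) and BPtchD-FLPlus (4, 5, 4). The splits decide nothing for Shh P30+ (0 genes by edgeR, 2383 at an unadjusted p under 0.05, 21 by DESeq2) and for BPtch tumours against P30+ cerebella (0 by edgeR, 1834 and 16), since all 60 splits call at least 0 genes, with highest others of 5203 and 2019. The splits treat libraries as exchangeable and so ignore shared animals and litters: the BPtch E16.5 embryos share 1 animal number, and so do the 5 BCP implants, so chance between libraries is excluded there and a difference between litters or donors is not. Drawing the labels anew also mixes the sexes. In the Wnt background at P5 and P30+, and for FLPlus in the Wnt and Shh backgrounds, the calls were largely sex chromosome genes. The splits do not tell the deletion from the sex of the groups there. Splits that called several times the real count point to a structure of those libraries other than genotype.

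For Ddx3x, Axin2 and Gli1, single libraries lay far from the others of their group in 12 of 144 tests, and chance flags about 1 in 20 groups. For Ddx3x these were BCP P5 replicate 1 (289.7 CPM), BD-FL-FL E16.5 replicate 2 (379.4), BDCP-FLFL E16.5 replicate 2 (513.5) and the library labelled BPtchD-FLY P5 replicate 2 (435.8). For Axin2 they were BDCP-FLFL P13 replicate 3 (156.9), BDCP-FLFL P5 replicate 3 (183.8) BDCP-FLY E16.5 replicate 4 (124.1), BD-FLPlus P30+ replicate 4 (46.42) and BD-FLPlus P5 replicate 4 (35.53). For Gli1 they were BPtchD-FLPlus P13 replicate 3 (72.21), BCP P13 replicate 1 (57.72) and BDCP-FLY P30+ replicate 1 (14.13).

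Differences of null groups from their controls differed between backgrounds by the interaction test. Strain stretches and shared reads stay open for genes such as Plac9a and Pcdhgb8, and litters for E16.5, so these differences are not read as effects of the deletion alone. Neighbouring tissue stays open as well, since these fits held no region scores. The midbrain score averaged -0.51 in BPtchD-FLY and 3.62 in BPtch at P5, but 3.21 in BD-FLY and 1.59 in WT. At P30+ it averaged -2.21 in BDCP-FLFL and 0.17 in BCP, but -0.21 in BD-FL-FL and -2.57 in WT. Between the Wnt and normal backgrounds the difference of both null genotypes, of FLY and of FL/FL differed for 291, 10 and 303 genes at E16.5, for 262, 26 and 553 at P13 and for 17, 1 and 267 at P30+. At P5 it differed for 2 genes in the mean of both and 282 in FL/FL. Between the Shh and normal backgrounds it differed for 2290 genes in FLY at P5, and at P13 for 1 gene in the mean of both and 1 in FL/FL. Named genes differed at E16.5 in the mean of both null genotypes, Wnt minus normal: Atm (-1.09), Dgki (-1.57), Kalrn (-1.18), Kcnq1ot1 (-1.06), Kmt2c (-0.86) and Ptar1 (-2.31). At P13 these were Catspere2 (1.26), Dgkh (-2.02), Myoc (4.12), Pcdhgb8 (2.02), Plac9a (-3.38), Plac9b (-3.37), Tfap2b (1.62) and Tmem254b (-1.59), and at P30+ Gadd45b (1.66). For FL/FL they were Ccng1 (-1.09) and Tnfrsf19 (-1.63) at P5, Axin2 (-1.28), Cd68 (-0.99), Ctss (-1.70), Kit (1.90) and Trem2 (-1.49) at P13, and Apcdd1 (-3.14), Notum (-3.53) and Wif1 (-4.86) at P30+.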

How the results depend on the processing

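The FL/FL to FLPlus contrast, the region scores and the listing run as a block were chosen after seeing the data. Of the counts under all alternatives 400 stayed within 1.5 times and 195 did not. Of 175 gene results, 4535 values kept their side of the threshold, 463 lost the call, 53 gained it and 2 reversed, and 3 had no value. Direction was compared only for genes called as reported or under the alternative. Sign changes of genes called in neither are counted among the 4535. Of 129 list results, 2806 values kept call and direction, 324 lost the call and 16 reversed. A list that lost its call with the sign of its median kept counts as having lost the call. Values of genes and lists for FL/FL against FLPlus were taken out of this comparison after many were seen to reverse, because it is another contrast, and its counts stay. Except where fewer libraries or another contrast make the difference, the cause was not tested.

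DESeq2 called 258, 121, 261 and 650 genes in the normal background at E16.5, P5, P13 and P30+, 36, 68, 158 and 25 in the Wnt and 369, 432, 353 and 21 in the Shh background. It called 106 and 57 for FLPlus in the normal and Wnt backgrounds, 2182 for BPtch against WT, 352 and 12 for the FLY and FLPlus Shh tumours and 16 for BPtch tumours against cerebella. With RLE size factors the FLY Shh tumours gave 5. With no low-count filter normal E16.5 gave 66, normal P30+ 51 and Wnt P13 5. With the replicate number as a block, normal E16.5, P5 and P13 gave 3, 10 and 6, Wnt P13 0, Shh E16.5 and P5 5 and 77, FLPlus 8 (normal) and 11 (Wnt), BCP 2169, BPtch 327, the Wnt implants 5194 and the FLPlus Shh tumours 0. With the animal number as a block normal E16.5 gave 123. With all 12 groups in 1 fit the normal background gave 371, 48, 230 and 12, Wnt E16.5, P5 and P13 13, 118 and 374, and Shh E16.5, P13 and P30+ 4, 10 and 3187. With the listing run as a block normal P5, P13 and P30+ gave 5, 88 and 41, Shh E16.5 7 and FLPlus in the normal background 41.

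FLY alone gave 2, 15 and 20 at E16.5, P13 and P30+ in the normal, 0, 0, 0 and 1 in the Wnt and 10, 4727 and 2 at E16.5, P5 and P13 in the Shh background. FL/FL alone gave 77, 291 and 86 at E16.5, P5 and P13 in the normal, 63, 5 and 64 at P5, P13 and P30+ in the Wnt and 6, 351 and 1209 at E16.5, P5 and P13 in the Shh background. FL/FL against FLPlus gave 0, 249, 4 and 0 in the normal, 0, 0, 0 and 96 in the Wnt and 0, 3.1e+02 (rounded) and 1692 at E16.5, P5 and P13 in the Shh background. With the region scores normal gave 72, 1, 90 and 2, Wnt P13 0, Shh 1, 49, 104 and 2, FLPlus 60 (normal) and 12 (Wnt) and BPtch 4059.

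In FLY alone the median of microglia markers was -0.066 at normal P5, -0.024 at Shh P5 and -0.051 at Shh P13, that of interferon genes -0.25 at normal P5, of Wnt targets 0.78 at Wnt P30+ and of inflammasome genes -0.14 at Shh P13, and Kit was at 0.094. In FL/FL alone Ddx3x was at 0.024 at normal P30+, and Shh targets at -0.14 and proliferation genes at -0.53 at Shh P5. With the region scores interferon genes were at -0.006 at normal P5, choroid plexus markers at 0.071 at normal P30+ and -0.12 at Wnt E16.5, and proliferation genes at -0.44 at Shh P5. With the animal as a block, vascular markers were at 0.076, Shh targets at -0.071 and granule progenitor markers at -0.047 in BPtch tumours against cerebella. Granule neuron markers at normal P13 ran from -0.071 without WT P13 replicate 3 to 0.415 without WT P13 replicate 1.

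With each library left out in turn, counts ran from 0 to 281, 0 to 19, 14 to 92 and 20 to 646 in the normal background, from 6 to 7, 6 to 37, 0 to 29 and 6 to 11 in the Wnt and from 3 to 36, 71 to 260 and 11 to 223 in the Shh background up to P13. At Shh P30+ edgeR called 0 each time. They ran from 13 to 60, 14 to 28 and 5 to 6 for FLPlus, 2781 to 4230 for BCP, 763 to 1953 for BPtch, 9053 to 10755 for the Wnt implants, 2 to 17 and 0 to 6 for the Shh tumours and 12078 to 12353 for development. The report names the libraries. Library totals differed widely, and simulated counts of edgeR at P13 recovered 38.8% of genes changed 1.5-fold, so small changes can be missed.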

Other observations

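The library labelled BPtchD-FLY P30+ replicate 1 had 614465 counts, with Xist at 308 CPM and Ddx3y at 99.3. The replicate numbers gave no pairing: in 0 of 22 comparisons did every same-numbered pair correlate above 0.1, with single correlations from -0.758 to 0.906. Animal numbers link some libraries and were used as a block for normal E16.5 and for BPtch tumours against cerebella, and not for the other groups they cross. Among pairs within the same group no library was a copy of another, with a lowest chi-square per degree of freedom of 4.73.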
